A study of Mus musculus with 6 samples.

How the data were processed

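RNA from mouse muscle stem cells was sequenced in 6 libraries, 2 for each of 3 genotypes: wild type (wt), mdx, and mdx with the change written in the labels as Ripk3mKO. The labels do not spell out mKO. The mdx mouse carries a mutation in the dystrophin gene and is a model of Duchenne muscular dystrophy. Per the labels' protocols, 10000 to 20000 sorted cells went into each library, made with version 2 of a Takara SMARTer kit for stranded total RNA at low input. Nothing in the labels says whether the 2 libraries of a group came from separate animals or cultures, so p-values measure the spread between these libraries, which may be technical.

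The deposited values are read counts per gene that were scaled between libraries and rounded to whole numbers, so they were treated as a score and not as raw counts. This reading rests on the values. Median-of-ratios size factors computed from the deposited table were 1.002 in every library and differed by at most 0.00039. Whole numbers between 1 and 40 were also skipped or doubled at regular steps within a column, as rounding after division leaves them. The submitters' processing notes name Trimmomatic 0.36, STAR 2.6.1d, featureCounts 1.6.3 from the Subread package, DESeq2 1.18.1 and the mm10 genome build, without the role of each step. Whether counting used strand is not given in the sources used here, so genes that overlap on opposite strands may share reads. The table listed 14515 genes, and each reached at least 10 in at least 1 library, per the deposited values. Both mdx columns carry one and the same header. They were used as the 2 mdx libraries, called library 1 and 2 in column order, and these numbers are names only.

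Totals of the scaled counts lay between 20611974 and 21037153. Scaling hides the depth, so divisors were estimated from the skipped and doubled whole numbers. They came to 0.909 and 0.870 for wt, 0.921 and 0.954 for mdx, and 1.204 and 1.206 for mdx/Ripk3mKO, the deepest libraries. Depth and genotype therefore go together for the mdx/Ripk3mKO libraries. A count of 0 allows up to 3 counts before scaling. With these divisors that is 2.49 to 3.45 scaled counts, or 0.118 to 0.167 CPM of the estimated totals, and it covers counting error only. Elsewhere CPM is the scaled count relative to the library total. No pair of libraries agreed within sampling noise: the mean chi-square per gene was 4.58 between the wt libraries, 5.29 between the mdx libraries and 8.65 between the mdx/Ripk3mKO libraries, so none was counted as a duplicate. The closest pairs lay between groups, wt library 1 with mdx/Ripk3mKO library 2 at 2.89 and wt library 2 with mdx library 2 at 4.37.

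A count model was planned for raw counts, with limma as the fallback before the data were examined. Because the values are scaled, limma 3.58.1 in R 4.3.3 was used on log2(scaled count + 1), with 1 fit over all 6 libraries and genotype as the only term. The fit left 3 residual degrees of freedom, and empirical Bayes moderation used a mean-variance trend and robust fitting with statmod 1.5.0. Genes with a scaled count of at least 10 in at least 2 libraries were tested, which kept 14077 and left out 438. This filter was set once the values were seen not to be counts, in place of the planned count filter, and the list tests used the same log2 values in place of log2 CPM. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Fold changes are on the log2(scaled count + 1) scale, which understates the change of low genes. Errors are the moderated standard errors unless SD is written.

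The comparisons were mdx against wt, mdx/Ripk3mKO against mdx, mdx/Ripk3mKO against wt, and an F-test over the 3 genotypes. Fixed before the data were examined were 20 gene lists and 12 cell type lists. Lists with at least 5 tested genes were tested with camera at a preset correlation between genes of 0.01, again with an estimated correlation, and with fry. The glycolysis list of 19 symbols gave 20 tested genes because Aldoa has 2 identifiers. The rule for named genes was also fixed then. Ripk3 and Dmd come first. In each comparison the 12 largest changes per direction follow, among genes past the threshold with a mean of at least 5 CPM, no overlap between the libraries compared, and a symbol that is not a predicted or clone name. Where fewer than 5 genes pass, the 10 smallest unadjusted p are named. Up to 4 members with the smallest p are named in each list. Not every gene that the rule selects is described here.

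The fit was tested on simulated negative binomial counts drawn around the real means of 14077 genes, in 5 runs with 200 changed genes each, for the comparison of mdx with wt. The changed genes were taken from those with a mean scaled count of at least 50. Recovery of lower genes such as Ripk3, or with fewer changed genes, was not simulated. With gene-by-gene spreads as fitted, 55.6% of genes changed 1.25-fold were recovered, 85.6% at 1.5-fold, 96% at 2-fold and 100% at 4-fold, and 12.8% of calls were false. With 1 spread for all genes, the false share was 7.43%. Both exceed the nominal 5%, so calls close to the threshold carry a higher error rate than their adjusted p states. The comparison of mdx/Ripk3mKO with wt was simulated without change. Over the 5 runs it gave 22 calls with gene-by-gene spreads and 1 with 1 spread for all genes. A few calls in a comparison can therefore arise without any change.

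Gene names and types come from the deposited table. Exon length and GC content were taken from GENCODE mouse release 21, whose build is that of the files. Of the listed identifiers 14502 were found there, and 10098 had the same coordinates. Coordinates in the text are the authors' and 1-based. Of 41 named or called genes, 6 overlapped another listed gene, 4 of them on the opposite strand, among them Map1a, Prr33 and Zc3h7a. AC160637.1 lies within Pkm, and Gm45867 overlaps Tm6sf1, so reads could be divided between them.

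The alternatives were no filter on low values, only the 2 groups compared, a replicate block, leaving out each library in turn, and leaving out mitochondrial, ribosomal RNA, haemoglobin and sex-linked genes. Added after seeing the data were a pseudocount of 5, trimmed mean and quantile scaling, moderation without trend or robust fitting, a loess correction of each library for GC content and exon length, and protein-coding genes only. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.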

Results

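Expression of 14515 genes was measured in 6 RNA libraries of mouse muscle stem cells, with 2 libraries each labelled wt, mdx and mdx/Ripk3mKO. Totals of the deposited scaled counts ranged from 20611974 to 21037153 per library. The sources give different accounts of the cells. The sample labels describe quiescent satellite cells, the resting stem cells of muscle, that were sorted and processed at once. The series text describes activated wild-type cells harvested after 72 hours below a transwell that held wt, mdx or mdx/Ripk3mKO cells. Under the second account the genotype is that of the cells above and not of those sequenced. The groups are therefore written as the libraries labelled wt, mdx or mdx/Ripk3mKO. The series title names the suppression of necroptosis, an inflammatory form of cell death that requires Ripk3, in stem cells of dystrophic muscle. How far the comparisons between labelled groups address that subject depends on which account of the cells holds.

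All 6 libraries held abundant transcripts of dividing and differentiating muscle cells. Myogenin (Myog), which drives terminal differentiation, lay between 1300 and 1700 CPM, its scaled count relative to the library total. The myogenic factor Myod1 lay between 904 and 1140 CPM, skeletal actin (Acta1) between 3170 and 4060, and the proliferation marker Mki67 between 660 and 820. Pax7, the defining transcription factor of satellite cells, lay between 84.6 and 103 CPM in the same libraries. The values of Myog, Acta1 and Mki67 argue against libraries made mainly of resting cells, as the sample labels describe them. They do not tell whether the genotype is that of the cells sequenced. Markers of blood cells were scarce. No gene of the neutrophil list or of the erythroid list was tested, 4 of 16 macrophage genes and 1 of 16 lymphocyte genes were.

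Ripk3 (ENSMUSG00000022221, mm10 chromosome 14, 55784996 to 55788857) did not separate the groups. Its scaled counts were 45 and 32 in the libraries labelled wt, 23 and 36 in those labelled mdx, and 17 and 33 in those labelled mdx/Ripk3mKO. The difference between mdx/Ripk3mKO and wt was -0.66 ± 0.34 on the log2 scale (95% interval -1.40 to 0.085, limma, adjusted p = 1), and that between mdx/Ripk3mKO and mdx was -0.27 ± 0.34 (adjusted p = 0.824). The value of a whole gene can miss a deletion of part of it. Dystrophin (Dmd, ENSMUSG00000045103, chromosome X, 82948903 to 85206141) was at 324 and 432 in wt, 531 and 692 in mdx, and 474 and 294 in mdx/Ripk3mKO. It was 0.69 ± 0.33 higher in mdx than in wt (adjusted p = 0.815). Neither gene checks the labels, and directions below rest on them.

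**Figure D1:**
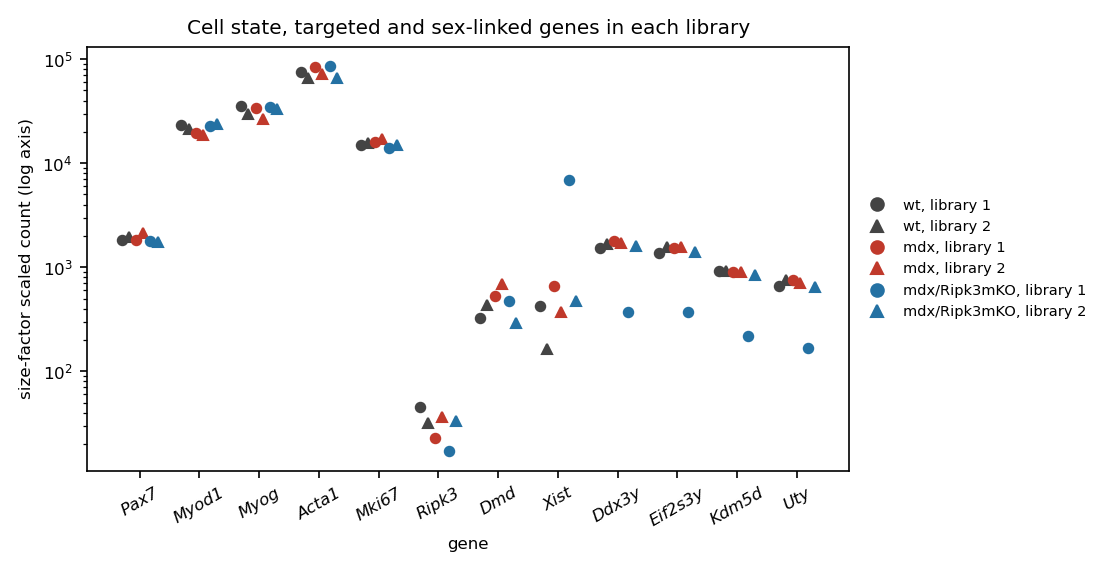
Scaled counts (log axis) of cell state genes, Ripk3, Dmd and sex-linked genes in each of the 6 libraries; each point is 1 library, coloured by its labelled group. Ripk3 overlaps between groups, and library 1 labelled mdx/Ripk3mKO stands apart in Xist, at 6918, and in the 4 Y-linked genes.

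One library differed from the rest in sex-linked transcripts. Library 1 labelled mdx/Ripk3mKO had 6918 scaled counts of Xist, the RNA that silences an X chromosome in female cells, against 164 to 666 in the other libraries. Its Y-linked Ddx3y, Eif2s3y, Kdm5d and Uty were at 373, 374, 216 and 167, which is 22.5%, 25.2%, 24.1% and 23.8% of the mean of the other libraries.

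Between the libraries labelled mdx and wt, Cdkn1c passed the threshold and was higher in mdx. Cdkn1c (ENSMUSG00000037664, chromosome 7, 143458339 to 143461050) encodes a cyclin-dependent kinase inhibitor that takes part in cell cycle exit. Its scaled counts were 486 and 488 in mdx against 300 and 272 in wt, a log2 fold change of 0.77 ± 0.10 (limma, adjusted p = 0.0182, n = 2 and 2). No gene was lower past the threshold. Unadjusted p-values under 0.05 were found for 909 of 14077 genes, 484 higher and 425 lower, where chance gives 704. The libraries of the 2 groups did not overlap for 35.92% of genes, and chance gives 33.33%.

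The other genes with the smallest p did not pass. Among them were values higher in mdx for Egr3, an immediate early transcription factor (1.28 ± 0.22), the insulin-responsive glucose transporter Slc2a4 (0.94 ± 0.19), Setbp1 (0.49 ± 0.09) and Amotl1 (0.30 ± 0.06). Values were lower in mdx for the adhesion molecule P-selectin (Selp, -0.64 ± 0.11), Adgrg3 (-0.50 ± 0.10), the proteoglycan Cspg4 (-0.41 ± 0.07) and the heparan sulfate proteoglycan Sdc3 (-0.30 ± 0.06). Their adjusted p lay between 0.19 and 0.254. Cdkn1c lost its call without wt library 1 or 2 or mdx library 1 or 2. It also lost the call without a variance trend or robust fitting. A fit of the 4 wt and mdx libraries alone called 93 genes higher and 10 lower. Fold changes between mdx and wt do not depend on the other libraries, and Cdkn1c stayed at 0.77. The fits therefore differ in the estimated spread and the genes tested. The mdx/Ripk3mKO libraries, left out there, were the least alike of the 3 pairs within a group (mean chi-square 8.65).

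Contractile and matrix genes stood higher in the libraries labelled mdx. All 14 tested genes of the mature myofibre list were higher than in wt, with a median of 0.30 (camera, adjusted p = 4.23e-10, and adjusted p = 0.763 with an estimated correlation), among them nebulin (Neb, 0.24 ± 0.08), the calcium pump Atp2a1 (0.31 ± 0.10) and the fast troponins Tnni2 (0.23 ± 0.08) and Tnnt3 (0.25 ± 0.10). Eno3 was at 0.00 ± 0.05. No gene of the list passed alone, over all genes or adjusted over the list alone. The estimated correlation between its genes was 0.584 against the preset 0.01, and fry gave the list an adjusted p of 0.623. In the list of myogenic activation and differentiation 16 of 21 genes were higher (median 0.23, adjusted p = 1.14e-05, and 0.763 with an estimated correlation). Neonatal myosin Myh8 was at 0.75 ± 0.24 and cardiac troponin Tnnt2 at 0.31 ± 0.12, while Myod1 was at -0.22 ± 0.05, Myog at -0.10 ± 0.15 and the fusion factors Mymk and Mymx at 0.02 ± 0.13 and 0.01 ± 0.16. Adjusted over the list alone, 1 gene was higher, Cdkn1c, and 1 lower, Myod1. In the extracellular matrix list 18 of 23 genes were higher (median 0.16, adjusted p = 4.81e-05, and 0.763 with an estimated correlation), with the basement membrane collagens Col4a1 at 0.22 ± 0.08 and Col4a2 at 0.20 ± 0.08. Pericyte and smooth muscle markers stood at a median of 0.41 in the same comparison, with 4 of 7 higher (adjusted p = 0.236). The dystrophin complex list had 17 of 19 genes higher (median 0.12, adjusted p = 5.79e-05, and 0.763 with an estimated correlation), with utrophin (Utrn) at 0.12 ± 0.05. The myogenic list did not pass without wt library 2 (median 0.12, adjusted p = 0.0555) or mdx library 1 (median 0.05, adjusted p = 0.171), nor the matrix list without wt library 1 (median 0.12, adjusted p = 0.0559).

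Mitochondrial and nuclear lists were also called in mdx against wt. All 12 mitochondrially encoded genes were higher (median 0.16, camera adjusted p = 6.77e-05), with mt-Rnr2 at 0.18 ± 0.06, as were 62 of 91 genes of oxidative phosphorylation (median 0.05, adjusted p = 0.00134), with Atp5k at 0.20 ± 0.06. Their adjusted p with an estimated correlation were 0.763 and 0.911. Of the NuRD list, a chromatin remodelling and deacetylase complex, 10 of 13 genes were lower (median -0.07, adjusted p = 0.0316, and 0.763 with an estimated correlation), with Gatad2a at -0.13 ± 0.06. Of the cell cycle list 21 of 26 were lower (median -0.05, adjusted p = 0.0345, and 0.911 with an estimated correlation), with Rrm2 at -0.11 ± 0.05, although Mki67 was at 0.11 ± 0.05. Single libraries ended each of these 4 calls. The mitochondrially encoded list did not pass without wt library 1 (median 0.08, adjusted p = 0.244), and after correction for GC content and exon length its median was 0.09 (adjusted p = 0.0208). Oxidative phosphorylation did not pass without wt library 2 (median 0.04, adjusted p = 0.0922) or mdx library 1 (median 0.02, adjusted p = 0.576). NuRD did not pass after correction for GC content and exon length (median -0.04, adjusted p = 0.0541) or without wt library 1 (-0.03, 0.279) or mdx library 2 (-0.05, 0.235), nor cell cycle without wt library 1 (-0.04, 0.104), wt library 2 (-0.04, 0.161) or mdx library 1 (-0.01, 0.841).

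The remaining lists gave no call in mdx against wt. The necroptosis list was not called (9 of 19 genes higher, median -0.01, camera adjusted p = 0.554), with Traf2 at -0.15 ± 0.08 and Fadd at 0.17 ± 0.12. None of its genes had an unadjusted p under 0.05 by limma. Fry for changes in either direction gave the list an unadjusted p of 0.0019. In mdx/Ripk3mKO against mdx and against wt that p was 0.134 and 0.179. In mdx against wt the same test gave 5.54e-05 for satellite cell identity and quiescence and 0.000935 for histones. These p were not adjusted over the lists. Camera adjusted p were 0.98 for apoptosis and for the Notch pathway, 0.655 for satellite cell identity and quiescence, 0.5 for immediate early genes, 0.46 for interferon response, 0.292 for NF-kappaB and cytokines, 0.102 for histones and 0.175 for ribosomal proteins. They were 0.967 for p53 and for glycolysis, 0.914 for antioxidant and 0.929 for autophagy genes. The immediate early list had a median of -0.03 and a mean of 0.11, with Egr3 its only member called adjusted over the list alone. Heyl, at 0.47 ± 0.09, was called adjusted over the Notch list alone, as was Jag2, at -0.20 ± 0.06.

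**Figure D2:**
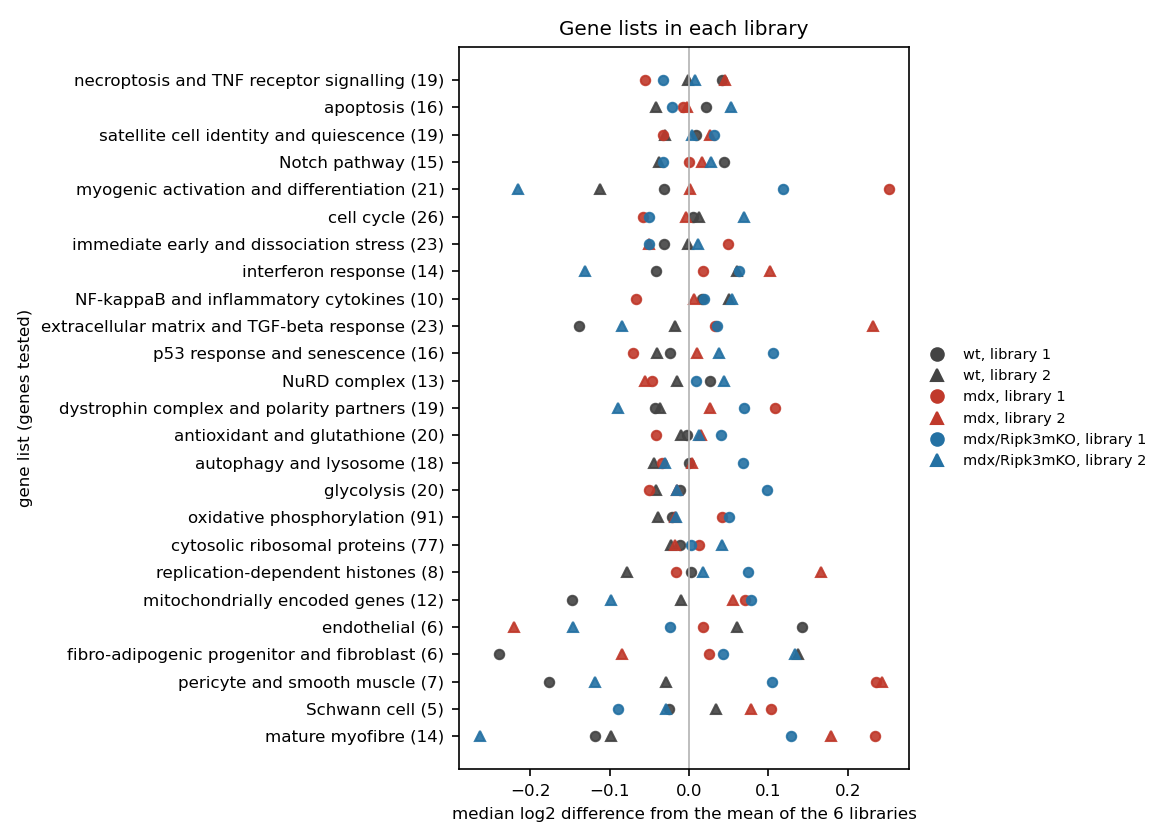
Median log2 difference of each gene list from the mean of the 6 libraries; each point is 1 library, coloured by its labelled group, with the number of genes tested in brackets. For the mature myofibre list both mdx libraries lie above both wt libraries, and the 2 mdx/Ripk3mKO libraries lie apart at 0.13 and -0.26.

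Between the libraries labelled mdx/Ripk3mKO and mdx, 12 genes were higher and 17 lower (limma, adjusted p under 0.05). Cdkn1c fell by 1.06 ± 0.10 on the log2 scale, to 230 and 236 scaled counts from 486 and 488 (adjusted p = 0.000326). Heyl (ENSMUSG00000032744, chromosome 4, 123233556 to 123249875), a transcriptional repressor induced by Notch, fell by 0.77 ± 0.09, to 1035 and 848 from 1502 and 1697 (adjusted p = 0.0162). Slc2a4 (ENSMUSG00000018566, chromosome 11, 69942543 to 69948164) fell by 1.22 ± 0.19, to 68 and 61 from 132 and 173 (adjusted p = 0.0223).

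The procollagen peptidase Adamts2 (-0.91 ± 0.16), the Wnt receptor Fzd4 (-0.49 ± 0.08), the junction protein Cgnl1 (-0.46 ± 0.06), Map1a (-0.43 ± 0.08), the transcription factor Zbtb20 (-0.41 ± 0.06), Serinc5 (-0.40 ± 0.07) and the imprinted gene Zim1 (-0.37 ± 0.06) were also lower. Egr3, named as a member of the immediate early list, was at -1.69 ± 0.22. Outside the rule for named genes fell 4 other lower genes, which are named after their values were seen: the glycogen-targeting phosphatase subunit Ppp1r3a (-1.37 ± 0.24), Gm45867 (-1.03 ± 0.18), AC160637.1 (-0.41 ± 0.07) and Zkscan3 (-0.33 ± 0.06). Higher in mdx/Ripk3mKO were Tmem200c (0.83 ± 0.13), Selp (0.65 ± 0.11), the laminin-binding integrin Itgb4 (0.47 ± 0.08), Cgref1 (0.46 ± 0.08), Cspg4 (0.44 ± 0.07), the osteoblast factor Sp7 (0.42 ± 0.08), Fam19a5 (0.37 ± 0.07), Sdc3 (0.35 ± 0.06), Dynap (0.35 ± 0.06), haem oxygenase Hmox1 (0.32 ± 0.05), argininosuccinate synthase Ass1 (0.31 ± 0.05) and thrombospondin Thbs1 (0.27 ± 0.05). Adjusted p of the 29 genes ran from 0.000326 to 0.0476. The libraries of the 2 groups did not overlap for 41.29% of all genes, where chance gives 33.33%. By limma 1638 genes had an unadjusted p under 0.05, where chance gives 704.

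**Figure D3:**
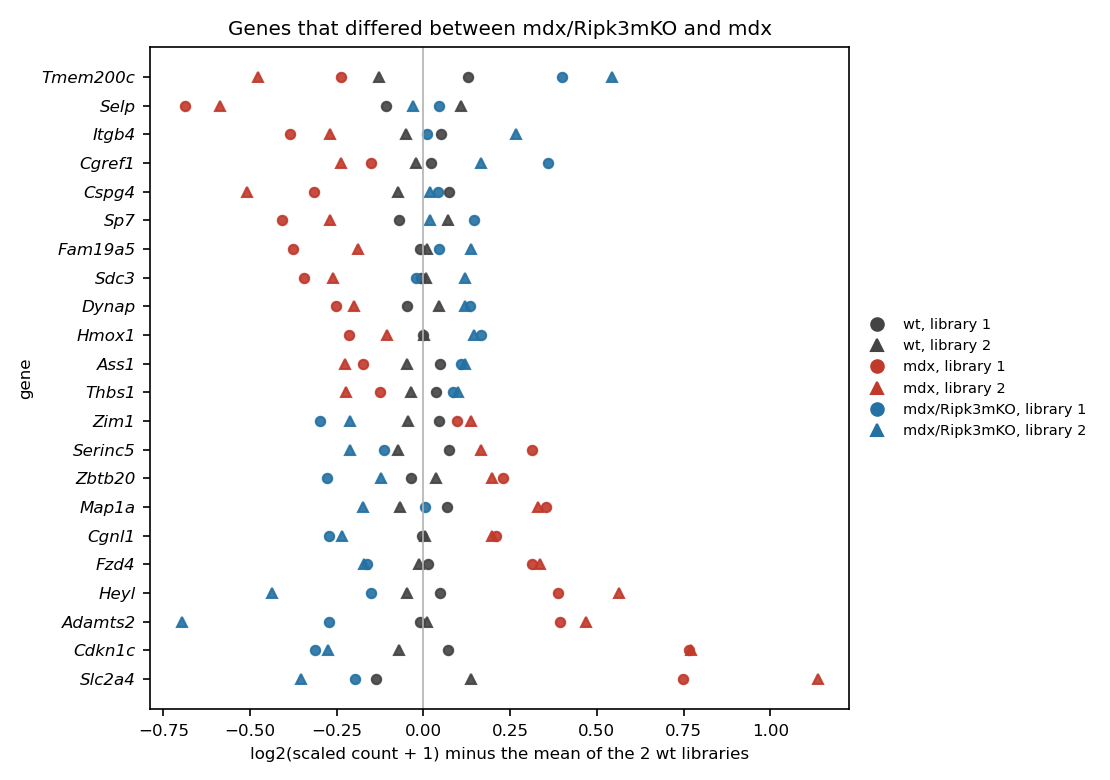
Genes described from those named by the fixed rule for mdx/Ripk3mKO against mdx, as log2(scaled count + 1) minus the mean of the 2 wt libraries; each point is 1 library, coloured by its labelled group. The genes were chosen because mdx and mdx/Ripk3mKO differ, so only the place of the wt libraries is free; Cdkn1c lies at 0.77 in mdx and -0.29 in mdx/Ripk3mKO.

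The count of 29 depended on single libraries. It was 2 without wt library 1 or without wt library 2, 13 and 1 without mdx library 1 and 2, and 278 and 28 without mdx/Ripk3mKO library 1 and 2. In the same order 2, 2, 6, 1, 26 and 9 of the 29 were still called. The calls without mdx/Ripk3mKO library 2 included the Y-linked Ddx3y, Eif2s3y, Kdm5d and Uty, since library 1 alone then stood for the group. Without a variance trend or robust fitting the count was 1, with 0 of the 29 still called, and with only the 2 groups compared it was 2. After correction for GC content and exon length it was 13, with 3 higher and 10 lower, all among the 29. All 29 kept their sign, with a median absolute log2 fold change of 0.41 after the correction against 0.44 before, and why the calls ended was not tested. Across 9813 protein-coding genes, which are not independent, the fold change between mdx/Ripk3mKO and mdx had a Spearman correlation of 0.41 with GC content and -0.24 with exon length.

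Of the lists that stood high in mdx, the myofibre, myogenic, matrix, dystrophin complex and mitochondrially encoded lists were lower in mdx/Ripk3mKO than in mdx, and oxidative phosphorylation was not (median 0.00, 46 of 91 genes higher). Both comparisons use the mdx libraries, so a list high in the first leans lower in the second even with no change. How far was not computed for lists. In the mature myofibre list 13 of 14 genes were lower (median -0.32, camera adjusted p = 1.41e-06, and adjusted p = 0.768 with an estimated correlation), with Neb at -0.37 ± 0.08, the only gene called adjusted over the list alone, titin (Ttn) at -0.34 ± 0.14, and Eno3, the muscle enolase, at 0.12 ± 0.05. The median was -0.47 without mdx/Ripk3mKO library 1 and -0.13 without library 2. In the myogenic list 15 of 21 genes were lower (median -0.17, adjusted p = 0.00135, and 0.845 with an estimated correlation). Adjusted over the list alone, Cdkn1c was lower and Myod1, at 0.28 ± 0.05, higher. In the matrix list 18 of 23 were lower (median -0.17, adjusted p = 0.000711, and 0.768 with an estimated correlation), with Col3a1 at -0.22 ± 0.07 and fibronectin (Fn1) at -0.28 ± 0.11. In the dystrophin complex list 15 of 19 were lower (median -0.08, adjusted p = 0.00612, and 0.768 with an estimated correlation), with Utrn at -0.13 ± 0.05. Without mdx library 1 the myogenic and dystrophin complex lists did not pass, at medians of -0.02 and -0.04 (adjusted p = 0.406 and 0.253). Without mdx/Ripk3mKO library 2 the myogenic, matrix and dystrophin complex lists did not pass, at medians of -0.04, -0.09 and -0.05 (adjusted p = 0.582, 0.123 and 0.25).

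Between mdx/Ripk3mKO and mdx 6 other lists were called. Lower were 11 of 12 mitochondrially encoded genes (median -0.06, camera adjusted p = 0.0396) and 4 of 5 sex-linked genes (median -1.10, adjusted p = 0.0396), which follow library 1. With an estimated correlation their adjusted p were 0.845 and 0.768. Higher were 12 of 13 NuRD genes (median 0.06, adjusted p = 0.0126), with Mbd3 at 0.17 ± 0.06, 12 of 16 genes of the p53 and senescence list (median 0.07, adjusted p = 0.0342), with Gdf15 at 0.37 ± 0.14, 49 of 77 cytosolic ribosomal protein genes (median 0.03, adjusted p = 0.0342), and 15 of 20 glycolysis genes (median 0.10, adjusted p = 0.0435). With an estimated correlation their adjusted p were 0.768 for NuRD and p53 and 0.845 for ribosomal and glycolysis genes. In the glycolysis list Hk1 was at 0.22 ± 0.06, Pkm at 0.15 ± 0.05 and Hk2 at -0.29 ± 0.07. Adjusted over the list alone, 4 of its genes were higher and 1 lower. With quantile normalization none of the 6 lists passed (camera, adjusted p = 0.0766 for NuRD). After correction for GC content and exon length NuRD alone of the 6 passed. The medians were then 0.01 for ribosomal genes (adjusted p = 0.756), 0.06 for glycolysis (0.491), 0.06 for p53 (0.109), 0.00 for mitochondrially encoded genes (0.892) and -1.03 for sex-linked genes (0.0991). Each call was lost without at least 1 of the libraries. Without mdx/Ripk3mKO library 1 the adjusted p was 0.913 for glycolysis, 0.21 for p53 and 0.125 for sex-linked genes. Without mdx/Ripk3mKO library 2 it was 0.123 for NuRD, 0.582 for ribosomal and 0.965 for mitochondrially encoded genes, whose median rose to 0.05. Without mdx library 1 it was 0.447 for glycolysis, 0.351 for p53, 0.127 for mitochondrially encoded and 0.254 for sex-linked genes, and without mdx library 2 it was 0.0884 for NuRD, 0.395 for ribosomal, 0.13 for mitochondrially encoded and 0.0884 for sex-linked genes. Without wt library 1 and 2 it was 0.0518 and 0.0533 for glycolysis, 0.0539 and 0.0554 for mitochondrially encoded and 0.164 and 0.163 for sex-linked genes.

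Other lists gave no call between mdx/Ripk3mKO and mdx. Within lists that did not move as a whole, the immediate early genes Egr2 and Fos were at -1.24 ± 0.37 and -0.60 ± 0.16, with adjusted p of 0.241 and 0.159. The necroptosis list stayed at a median of 0.01 (10 of 19 genes higher, adjusted p = 0.865), with its effector Mlkl at 0.25 ± 0.14. In the apoptosis list (adjusted p = 0.651) Bcl2, which restrains cell death, was at -0.60 ± 0.16 and Bax, which promotes it, at 0.21 ± 0.06. Adjusted over the list alone Bax was higher and Bcl2 lower. Camera adjusted p were 0.865 for satellite cell identity and quiescence, 0.785 for the Notch pathway, 0.157 for cell cycle, 0.527 for immediate early genes, 0.74 for interferon response, 0.339 for NF-kappaB and cytokines, 0.223 for antioxidant, 0.242 for autophagy, 0.798 for oxidative phosphorylation and 0.916 for histone genes.

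Between the libraries labelled mdx/Ripk3mKO and wt no gene passed in either direction (limma, smallest adjusted p = 0.0799), and 468 genes had an unadjusted p under 0.05, fewer than the 704 that chance gives. Their libraries did not overlap for 29.43% of genes, and chance gives 33.33%. The genes with the smallest p under the fixed rule were all lower in mdx/Ripk3mKO and did not pass. They were Zkscan3 (-0.31 ± 0.06), Prr33 (-0.49 ± 0.11), Uvssa (-0.36 ± 0.08), Zim1 (-0.25 ± 0.06), Cgnl1 (-0.25 ± 0.06), Zfp715 (-0.35 ± 0.09), the p53 regulator Mdm4 (-0.23 ± 0.06), Zc3h7a (-0.23 ± 0.06), Ccnt2 (-0.24 ± 0.07) and Zfp280c (-0.23 ± 0.07). Without mdx/Ripk3mKO library 2 that group rested on library 1 alone. Genes then passed in both directions, among them the Y-linked Eif2s3y, Kdm5d and Uty, at -1.96, -2.08 and -2.08.

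Lists of protein synthesis and metabolism were slightly higher in mdx/Ripk3mKO than in wt. Higher were 67 of 77 cytosolic ribosomal protein genes (median 0.05, camera adjusted p = 1.7e-07), 69 of 91 genes of oxidative phosphorylation (median 0.05, adjusted p = 2.94e-05), 14 of 16 genes of the p53 and senescence list (median 0.06, adjusted p = 0.00128), with Sesn2 at 0.20 ± 0.08, 18 of 20 glycolysis genes (median 0.06, adjusted p = 0.00195), 18 of 20 antioxidant genes (median 0.04, adjusted p = 0.0181), with Hmox1 at 0.16 ± 0.05, and 11 of 18 autophagy and lysosome genes (median 0.04, adjusted p = 0.0297), with the cathepsins Ctsb at 0.16 ± 0.06 and Ctsd at 0.15 ± 0.06. With an estimated correlation their adjusted p were 0.793 for ribosomal, p53 and antioxidant genes and 0.845 for the other 3 lists. Of the 5 sex-linked genes 4 were lower (median -1.07, adjusted p = 0.0203, and 0.793 with an estimated correlation). Glycolysis, oxidative phosphorylation, antioxidant and autophagy did not pass without mdx/Ripk3mKO library 1, at medians of 0.00, 0.02, 0.04 and 0.00 (adjusted p = 0.776, 0.368, 0.0831 and 0.848). Without mdx/Ripk3mKO library 2 the medians were 0.02 for ribosomal genes (adjusted p = 0.0302), 0.16 for p53, 0.11 for glycolysis and 0.08 for oxidative phosphorylation and autophagy, all still called. Antioxidant and autophagy also did not pass without wt library 2 (0.235 and 0.681), nor autophagy without mdx library 1 or 2 (0.0598 and 0.0594). The sex-linked list did not pass without mdx/Ripk3mKO library 1 (0.589), wt library 1 or 2 (0.334 and 0.226) or mdx library 1 or 2 (0.0639 and 0.0647). The fold change between mdx/Ripk3mKO and wt had a Spearman correlation of -0.32 with exon length and 0.29 with GC content across the same genes, and after the correction for both the p53 list alone of these 6 passed (adjusted p = 0.00954). The medians of ribosomal, glycolysis and oxidative phosphorylation genes were then 0.02, 0.03 and 0.01 (adjusted p = 0.0792, 0.0596 and 0.0792). The mature myofibre list was not called against wt (9 of 14 genes higher, median 0.05, adjusted p = 0.802), but its libraries stood apart. Its median deviation from the mean of all libraries was 0.13 and -0.26 in mdx/Ripk3mKO library 1 and 2, against -0.12 and -0.10 in wt. The necroptosis list was not called (adjusted p = 0.684). Camera adjusted p were 0.585 for apoptosis and NuRD, 0.602 for the Notch pathway, 0.79 for cell cycle and immediate early genes, 0.694 for interferon response, 0.872 for NF-kappaB and cytokines, 0.114 for histones and 0.299 for mitochondrially encoded genes. They were 0.802 for the satellite cell, myogenic, matrix and dystrophin complex lists. The matrix list had a positive median with a test pointing down, and the dystrophin complex list a negative median with a test pointing up.

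The F-test over the 3 genotypes called 11 genes, among them Cdkn1c (adjusted p = 0.00099), Egr3, Cgnl1, AC160637.1, Heyl, Zbtb20, Slc2a4, Cspg4, Selp and Sdc3. One gene, Cdkn1c, was called in mdx against wt and in the opposite direction in mdx/Ripk3mKO against mdx. Both comparisons use the same mdx libraries, and 100 simulations with unchanged groups gave a mean of 1.22 such genes and at most 4, while independent lists would share 0.00121. Of the 29 genes called between mdx/Ripk3mKO and mdx, 28 had the opposite sign in mdx against wt, and the 29 smallest p in the simulations gave a mean of 26.4 with a range of 20 to 29. Across 10006 genes, which are not independent, the fold changes of the 2 comparisons correlated at -0.756 against a simulated -0.503, and their covariance was -0.016 against a simulated -0.00652, a difference of -0.00949. The simulation drew each gene independently. Shifts common to many genes in the shared mdx libraries, which are too few to divide, could therefore give part or all of the excess. For the comparisons that share the wt libraries, the correlation was 0.189 against a simulated 0.512 and the covariance 0.00266 against a simulated 0.00665.

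The cell type lists gave no call in any comparison except the mature myofibre and sex-linked lists. In mdx against wt the camera adjusted p were 0.83 for endothelial genes (6 tested), 0.967 for fibro-adipogenic progenitor genes (6 tested), 0.236 for pericyte and smooth muscle genes (7 tested) and 0.552 for Schwann cell genes (5 tested). Between mdx/Ripk3mKO and mdx they were 0.865, 0.66, 0.682 and 0.339 in the same order, and between mdx/Ripk3mKO and wt 0.684, 0.694, 0.585 and 0.694. In mdx against wt, adjusted over the pericyte list alone, Pdgfrb (0.41 ± 0.12) and Mustn1 (0.53 ± 0.17) were higher and Cspg4 (-0.41 ± 0.07) lower. Tenocyte (3 tested) and adipocyte (2 tested) genes were too few for a test, with Scx at -0.09 ± 0.07 and Lpl at 0.35 ± 0.09.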

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

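The pseudocount, trimmed mean and quantile scaling, variance model, GC content and length correction and protein-coding alternatives were chosen after seeing the data. No filter, a pseudocount of 5 and trimmed mean scaling left every count of genes and lists within 1.5 times its value. Without a variance trend or robust fitting, mdx/Ripk3mKO against mdx gave 0 genes up and 1 down and the F-test 1. None of the 29 genes was still called, and the 1 gene called in mdx against wt was not Cdkn1c. With the GC content and length correction there were 3 up and 10 down in mdx/Ripk3mKO against mdx, 4 by F-test, lists 1 down in mdx against wt, 1 up in mdx/Ripk3mKO against mdx, and 2 up and 0 down in mdx/Ripk3mKO against wt. The mitochondrially encoded list in mdx/Ripk3mKO against mdx came to a median of 0 (adjusted p = 0.892). With protein-coding genes only, 11 were down in mdx/Ripk3mKO against mdx and 2 called by F-test, with lists 1 up in that comparison and 0 down in mdx/Ripk3mKO against wt. Quantile normalization gave 0 lists down in mdx against wt and 0 up in mdx/Ripk3mKO against mdx. Leaving out mitochondrial, ribosomal RNA, haemoglobin and sex-linked genes gave 2 lists up in mdx/Ripk3mKO against mdx and 0 down in mdx/Ripk3mKO against wt, where the sex-linked list itself is removed. With only the groups compared in the fit, mdx against wt gave 93 up and 10 down, mdx/Ripk3mKO against mdx 0 up and 2 down, 2 genes changed in opposite directions, and 0 lists were down in mdx/Ripk3mKO against wt. With an estimated correlation 0 lists were up and 0 down in all 3 comparisons. Fry as a directional test also called 0 lists in each of them. Except where stated, the cause was not tested.

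Leaving out each library in turn gave 0 to 93 genes up and 0 to 11 down in mdx against wt, 0 to 40 up and 1 to 238 down in mdx/Ripk3mKO against mdx, and 0 to 11 up and 0 to 9 down in mdx/Ripk3mKO against wt. The F-test gave 1 to 203 and opposite directions 0 to 101. The highest counts came without mdx/Ripk3mKO library 1 or 2. In the comparisons of mdx/Ripk3mKO with mdx and with wt, the calls without library 2 included Y-linked genes. Lists ran from 4 to 8 up and 0 to 2 down, 2 to 4 up and 2 to 5 down, and 3 to 11 up and 0 to 4 down in the same order. A group left with 1 library is assumed to vary like the others. The autophagy and lysosome list in mdx/Ripk3mKO against wt ran from 0.0027 without mdx/Ripk3mKO library 1 (adjusted p = 0.848), with its test pointing down, to 0.0845 without library 2. The cause was not tested.

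The replicate block was fitted to the 4 wt and mdx/Ripk3mKO libraries only and gave 0 genes up, 0 down, and lists 6 up and 1 down. Library numbers were not shown to pair, with a correlation of 0.009 across 10006 genes. Genes named by the fixed rule were followed under the alternatives, with list members included only where camera had called the list. Of their 2236 values, 1995 stayed on their side of the threshold, 183 lost the call, 58 gained one and 0 called values changed sign. Of the 1995, 5 uncalled values changed sign. All 29 genes kept their sign wherever tested. Their mdx and mdx/Ripk3mKO libraries did not overlap, so leaving out a library could not change a sign. Cdkn1c in mdx against wt was called in 10 of 15 alternatives (adjusted p 0.00164 to 0.735), and in mdx/Ripk3mKO against mdx in 14 of 15 (0.000101 to 0.295). DESeq2 and edgeR fits were not run because they need counts, nor was other size-factor scaling, which the values already carry.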

Other observations

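Of the tests here, those on the spread within a group, fibro-adipogenic genes, cells of both sexes, a female library and the Y-linked share of library 2 were chosen after the result was seen.

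Transcripts annotated as unspliced or of uncertain coding status were lower in the libraries labelled mdx/Ripk3mKO. Of 286 tested TEC (an annotation class of unproven genes) and sense-intronic genes, 217 were lower than in wt, with a median of -0.29, and the median in mdx against wt was 0.05. They made up 0.046% and 0.051% of the total in mdx/Ripk3mKO against 0.058% and 0.062% in wt.

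Contractile genes were higher in the libraries labelled mdx by a median of 0.30. Correction for GC content and exon length left the median at 0.298, which argues against that bias as the cause. Fibro-adipogenic genes had a median of 0.012 against 0.16 for the matrix list, with a standard deviation of 0.125 over 6 genes that went both ways, which argues only weakly against such cells behind the collagens. Pericytes were not tested as their source and stay open, with a median of 0.41 over 7 genes that went both ways. A spread of differentiation between libraries could be large enough, since the mdx/Ripk3mKO libraries differed from each other by 0.401, although the wt and mdx pairs differed by -0.017 and 0.053. An effect of genotype, or of the co-culture described in the series text, stays open.

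Library 1 labelled mdx/Ripk3mKO had more Xist and fewer Y-linked transcripts than the rest. The 4 Y-linked genes lay at a common share of their level elsewhere, the highest 1.12 times the lowest, which is consistent with cells of both sexes in that library. The lowest share was 22.5%, too high for a library from females only. Without that library the 29 genes called between mdx/Ripk3mKO and mdx kept 102% of their median absolute log2 fold change. The 29 were chosen with both libraries and passed where these were alike. The choice thus largely fixed this outcome, which cannot decide on sex as their source. A change in library 1 alone does not pass easily, since the 4 Y-linked genes were not called (limma, adjusted p 0.683 to 0.707). Library 2 held 89.3% to 94.7% of the wt and mdx mean of these 4 genes. A contribution of sex in library 1 stays open. How the cells came together was not tested.

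For the lower TEC and sense-intronic transcripts, the median against wt was -0.304 after correction for GC content and exon length. The correction was fitted on more abundant genes only, and 21 of 286 of these transcripts had a mean of at least 100. The corrected median therefore argues only weakly against that bias. Before correction the median was -0.327 in the 21 genes with a mean of at least 100, which argues against rounding of low values at a greater depth. Batch, depth and carry-over of unspliced RNA or DNA go together with the group, so they cannot be told apart here and were not tested.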
